A study of Mus musculus with 10 samples.

How the data were processed

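Whole-lung RNA of 10 mice was sequenced, 5 with floxed Ern1 alleles and no Cre (Flox) and 5 in which the same floxed alleles were combined with Cre under the Shh promoter (EpithelialKO). Ern1 encodes IRE1α, the endoplasmic reticulum kinase and ribonuclease that splices Xbp1 mRNA. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was captured on oligo(dT) beads and fragmented, and cDNA was primed with random hexamers. Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with HISAT2, and the genome build was GRCm38; versions are not given in the sources used here. The counting tool, the annotation counted on, its strand setting and its treatment of reads that map to several genes are not given there either. The deposited values are whole-number counts per Entrez gene, with 1 column per mouse and no normalization, as read from the values. Genes that overlap or have near-identical copies may therefore share reads.

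The table held 27179 Entrez genes, of which 25275 matched a symbol in the RefSeq table of the same build, GRCm38, which also gave the coordinates printed. The total per mouse lay between 14983829 and 21224412 counts. All pairs of mice differed by more than counting noise: the lowest chi-square per degree of freedom between 2 mice was 17.8, so each mouse counted as 1 sample. Mouse numbers are not shared between the groups and nothing in the labels pairs the mice. The labels give no sex, age or batch.

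Genes with low counts were removed with filterByExpr at its defaults, which left 15301 genes. Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 of EpithelialKO over Flox, and their standard errors were derived from the F statistic. Expression is given as CPM after TMM, as the mean ± SD of the mice of a group.

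Before the data were examined, 44 gene lists were fixed for cell types, stress pathways, inflammation, metabolism and technical factors, and 43 had at least 3 tested members. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The test was repeated with a correlation estimated per list. A list score, the mean log2 CPM (prior count 2) of the tested members, was computed per mouse and compared by an exact two-sided permutation test over the 252 assignments of the mice to groups of 5, whose smallest possible p is 0.00794. Counts of list members are given after adjustment over all genes and after adjustment over the list alone.

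The rule for named genes, fixed at the same point, always named Ern1, Ern2, Xbp1 and Shh. It then took up to 12 genes per direction past the threshold that were not predicted models, reached 1 CPM in a group and lay on one side of the Flox mean in all 5 EpithelialKO mice. For each list described it took up to 4 members with the lowest p. Genes named outside the rule are said to have been chosen after their values were seen.

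Alternatives planned then were other scalings (DESeq2 size factors, upper quartile), the Wald test of DESeq2 1.42.0, limma-voom with sample weights, no count filter, a filter of 1 CPM in 5 mice, leaving out each mouse, 1 surrogate variable (sva 3.50.0), removal of blood, heart, fat and immunoglobulin genes, a threshold of 0.1, and for the list scores a prior count of 0.5 and z scores. Alternatives added after seeing the data were a fit without Flox mice 4 and 6, which had high Xist and no Y-linked counts, sex class and the cardiac, adipose and erythroid list scores as covariates, and an offset per mouse on transcript length and GC content, available for 93.5% of the tested genes. Of these, the fits with sex class and the cardiac score had been set down beforehand as tests of explanations for the called genes.

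The gene and list tests were tested on simulated data made from the means, dispersions and library sizes of this comparison of EpithelialKO with Flox, on 15301 genes with 200 changed per run in 3 runs. Of the changed genes, 38.8% were recovered at a fold of 1.5, 63.2% at 2 and 87.9% at 4, and 3.32% of the calls were genes simulated as unchanged. All 6 lists moved by a fold of 1.3 were called with either correlation and no other list was. The simulated genes were drawn independently, so the simulation does not cover correlation between genes.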

Results

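The series compared whole lungs of mice in which Cre expressed from the Shh locus removes floxed Ern1 from the lung epithelium with lungs of floxed mice that carry no Cre. The question was how the transcriptome of the whole lung differs when the epithelium lacks IRE1α. There were 5 Flox and 5 EpithelialKO mice, each a separate animal. Totals ranged from 14983829 to 21224412 counts in Flox and from 16234895 to 18870247 in EpithelialKO. Flox mouse 5 had the lowest total and the lowest sample weight in limma-voom, 0.479. The surfactant gene Sftpc took the most counts in 9 of the mice and the club cell secretoglobin Scgb1a1 in EpithelialKO mouse 17. Flox mice 4 and 6 had 3949 and 4866 Xist counts and 0 Y-linked counts, whereas the other 3 Flox mice and all 5 EpithelialKO mice had 2 to 61 Xist counts and 2462 to 3575 Y-linked counts. Xist is transcribed from the inactive X chromosome, so the groups differed in this measure of sex.

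Hedgehog target genes and genes of the IRE1-XBP1 secretory pathway fell in EpithelialKO lungs, by median log2 fold changes of -0.61 and -0.12 (camera adjusted p = 4.2e-07 and 9.23e-05; adjusted p = 0.0405 with an estimated correlation for both, and 0.0871 for both without Flox mice 4 and 6). Neither passed the exact permutation test after adjustment (adjusted p = 0.0683), although both had the smallest p that this test can give, 0.00794. Lists of collagen and matrix, fibroblast, smooth muscle and endothelial genes fell, with medians from -0.44 to -0.27, and lists of AT2, club, ciliated and pan-epithelial genes rose, with medians from 0.25 to 0.41. These 8 calls were lost with an estimated correlation (camera adjusted p from 0.0695 to 0.303). Of single genes, 6 passed the threshold, with Gclc higher and Il2rb, Emilin1, Rasgrp3, Specc1l and Sdc3 lower. None of them passed in edgeR without Flox mice 4 and 6, with sex class (which sets apart the same mice) or the adipose score as a covariate, or in 9 of the 10 fits that left out a mouse. With an offset on transcript length and GC content 2 of them passed.

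Ern1 counts did not separate the groups. Ern1 (Entrez 78943, GRCm38 chromosome 11, 106397620 to 106487796) stood at 16.8 ± 5.28 CPM (SD, n = 5) in Flox and 17.3 ± 6.52 CPM (SD, n = 5) in EpithelialKO, a log2 fold change of 0.04 ± 0.27 (SE) with an edgeR adjusted p of 0.975. Its 95% interval ran from -0.55 to 0.63. Flox mouse 5 had the lowest value, 8.05 CPM, and EpithelialKO mice 22 and 21 had the highest, 26.1 and 21.8 CPM. The log2 fold change was -0.13 without Flox mouse 5 and ranged from -0.16 to 0.17 over the fits that left out 1 mouse. The labels do not say which exons are floxed, the counts cover the whole gene, and whole lung also holds cells that keep Ern1, so these counts do not check the genotype labels. "EpithelialKO" below therefore refers to the libraries so labelled. Xbp1, the transcription factor whose mRNA IRE1α splices, had a log2 fold change of 0.04 ± 0.11 (SE, edgeR adjusted p = 0.938), but gene counts do not distinguish its spliced form. Shh, the locus that carries Cre, was at 17.4 ± 4.86 CPM (SD, n = 5) in Flox and 17.1 ± 5.54 CPM (SD, n = 5) in EpithelialKO, with a log2 fold change of -0.03 ± 0.22 (SE). Ern2, which encodes the IRE1β paralog of mucous cells, was not tested: it had 5 counts over the Flox mice and 0 over the EpithelialKO mice.

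Of the 15301 genes tested, 6 passed the threshold, 1 higher and 5 lower in EpithelialKO, all at an edgeR adjusted p of 0.0272. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis (Entrez 14629, chromosome 9, 77754535 to 77794489), rose from 191 ± 21.3 to 294 ± 26.1 CPM (SD, n = 5 each), a log2 fold change of 0.62 ± 0.10 (SE). Il2rb, the beta chain of the IL-2 and IL-15 receptors of T and NK cells (Entrez 16185, chromosome 15, 78479256 to 78511621), fell from 27.1 ± 3.75 to 14.4 ± 2.10 CPM (log2 fold change -0.92 ± 0.14, SE). Emilin1, an elastic fibre glycoprotein (Entrez 100952, chromosome 5, 30913387 to 30921279), fell from 47.2 ± 9.49 to 26.0 ± 3.16 CPM (-0.86 ± 0.14). Rasgrp3, a guanine nucleotide exchange factor for Ras and Rap (Entrez 240168, chromosome 17, 75435870 to 75529054), fell from 94.7 ± 9.01 to 58.8 ± 8.91 CPM (-0.69 ± 0.11). Specc1l, a cytoskeletal protein (Entrez 74392, chromosome 10, 75212037 to 75312400), fell from 185 ± 13.8 to 130 ± 4.93 CPM, with a log2 fold change of -0.51 ± 0.08. The syndecan Sdc3 (Entrez 20970, chromosome 4, 130792537 to 130826318) fell from 129 ± 5.19 to 90.5 ± 3.37 CPM, with a log2 fold change of -0.51 ± 0.08. In each of the 6 genes all 5 EpithelialKO mice lay on the same side of the Flox mean.

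**Figure D1:**
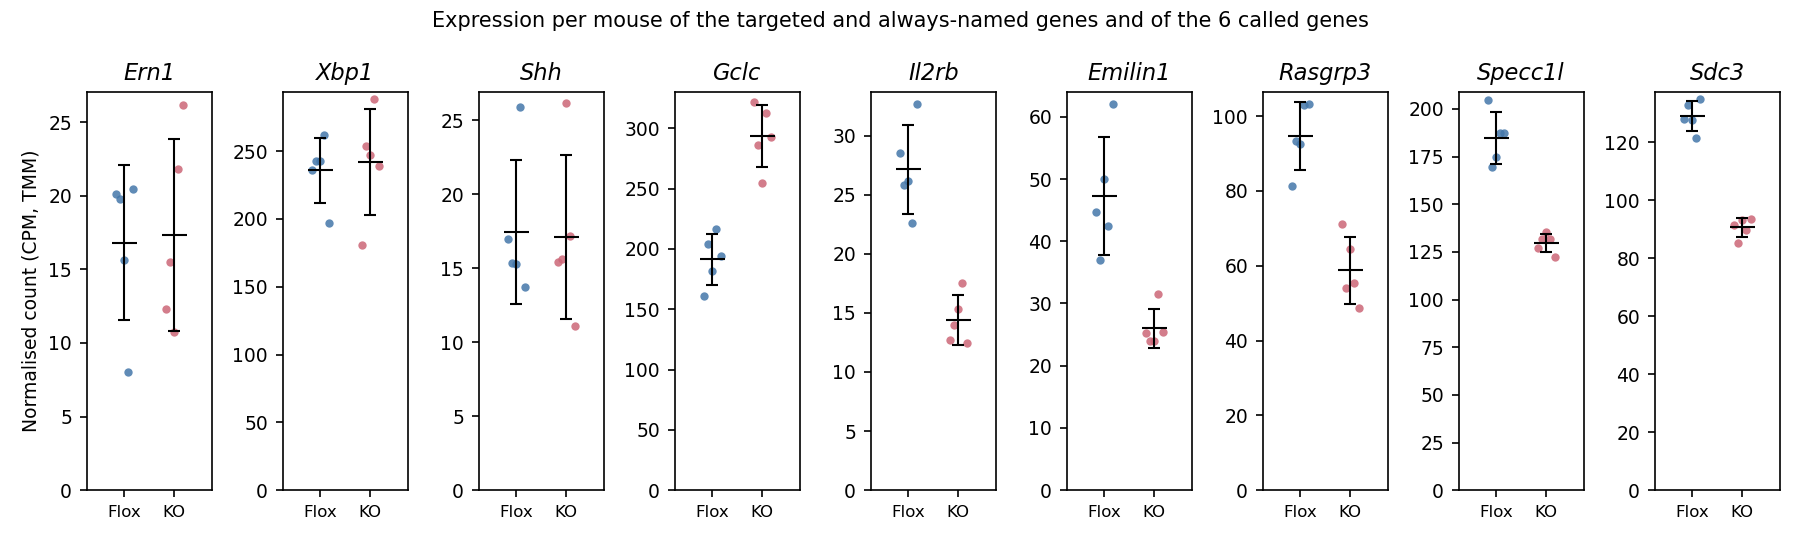
Normalised counts (CPM after TMM, linear axes from 0) of 9 genes per mouse, with Flox in blue and EpithelialKO in red, black dashes for group means and bars for SD (n = 5). Ern1, Xbp1 and Shh overlap between the groups, while in the 6 genes past the threshold the 5 EpithelialKO mice lie apart from the 5 Flox mice.

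The counts of changed genes were sensitive to leaving out single mice. Leaving out any mouse other than Flox mouse 5 gave 0 calls in edgeR, with 1444 to 1960 genes at an unadjusted p under 0.05, while leaving out Flox mouse 5 gave 48. In the fits with 0 calls for a single mouse left out, the lowest adjusted p lay between 0.0535 and 0.109. Those fits also hold fewer mice, so they do not show that particular mice carry the calls. The fit without Flox mice 4 and 6 and the fit with the adipose score as a covariate also gave 0 calls, at 1207 and 1589 genes of an unadjusted p under 0.05, and the DESeq2 Wald test gave 275 on all 10 mice, 106 higher and 169 lower. At an unadjusted p under 0.05 there were 1896 genes, a number that 5 of 100 splits of the mice into groups of 5 reached, the real split included. All 5 EpithelialKO values lay beyond all 5 Flox values in 477 genes (3.12%), against an average of 0.794% over random groups. Genes are not independent and this share was not counted in the other splits, so it does not exclude chance.

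Of the 43 lists tested, 26 were shifted in camera with the preset correlation, 13 higher and 13 lower in EpithelialKO. With an estimated correlation 2 remained past the threshold, the hedgehog targets and the IRE1-XBP1 secretory pathway. By the exact permutation test of the list scores per mouse, none passed after adjustment (lowest adjusted p = 0.0683), and 13 had an unadjusted p under 0.05. In 5 lists the groups did not overlap and the unadjusted p was the smallest possible, 0.00794. No wider separation of the groups could have lowered the p of those lists. The sentences below that say a list rose or fell refer to the preset correlation, and give the adjusted p with an estimated correlation beside it. The lists of matrix, fibroblast, smooth muscle and endothelial genes had 55 of 58 tested members with a negative fold change, and the 4 lists of AT2, club, ciliated and pan-epithelial genes had 78 of 79 with a positive one. The other epithelial lists were mixed. Positive members were 6 of 17 for AT1, 10 of 15 for the Krt8-high transitional, 12 of 16 for the mucous and 5 of 7 for the neuroendocrine list. The remaining stromal list, of mesothelial markers, had 7 of 7 negative.

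The hedgehog target list fell, with a median log2 fold change of -0.61 over 8 members, all negative (camera adjusted p = 4.2e-07; adjusted p = 0.0405 with an estimated correlation). None of the 8 passed over all genes and 5 were lower when adjusted over the list alone. Hhip, an inhibitor that hedgehog signalling induces, went from 17.6 ± 4.89 to 8.45 ± 1.67 CPM (SD, n = 5 each), a log2 fold change of -1.06 ± 0.21 (SE). Gli1, the transcriptional effector, had -0.96 ± 0.30, the receptor component Smo -0.54 ± 0.16, and the mesenchymal transcription factor Foxf1 -0.46 ± 0.15. All 5 EpithelialKO scores lay below all 5 Flox scores. Hhip is also a member of the smooth muscle list. Without Flox mice 4 and 6 the median was -0.45 and the adjusted p with an estimated correlation was 0.0871.

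The IRE1-XBP1 secretory pathway list, genes of protein translocation, folding and degradation in the endoplasmic reticulum that XBP1 activates, fell by a small amount. Its median log2 fold change was -0.12, with 31 of 40 members negative (camera adjusted p = 9.23e-05; adjusted p = 0.0405 with an estimated correlation), and the scores of the groups did not overlap. No member passed over all genes. Adjusted over the list alone, 1 member was lower, the translocon-associated Ssr1 (-0.36 ± 0.09, SE, 125 to 97.4 CPM). The mannosidase-like Edem1 had -0.31 ± 0.10, the translocon channel Sec61a1 -0.25 ± 0.08 and the disulfide isomerase Pdia5 -0.45 ± 0.16, none past either threshold. Without Flox mice 4 and 6 the median was -0.13 and the adjusted p with an estimated correlation was 0.0871. The list of ATF6-linked chaperones and degradation genes was not shifted (median 0.08, camera adjusted p = 0.94). Within it Atf6 was lower when adjusted over the list alone (-0.40 ± 0.11), and the chaperone Hspa5 had 0.34 ± 0.12 without passing. The list of transcripts described as substrates of IRE1-dependent decay fell (median -0.23, 11 of 13 negative, camera adjusted p = 0.0158; adjusted p = 0.17 with an estimated correlation), and lost its call without Flox mouse 6 and with sex class as a covariate. The median was -0.09 without Flox mice 4 and 6 and -0.15 without EpithelialKO mouse 20. Less IRE1-dependent decay would raise its substrates, so the fall of this list ran the other way. Its member lower over the list alone was Pdgfrb (-0.62 ± 0.16), a receptor of pericytes and fibroblasts, whereas Bloc1s1, the commonly used substrate, stood at 63.6 CPM in Flox and 77.5 CPM in EpithelialKO (0.28 ± 0.11) without passing. Sparc and Col6a1 are on both this list and the matrix list, and Per1 is on this list and the circadian list.

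Stromal and vascular lists fell. Fibrillar collagen and matrix genes had a median log2 fold change of -0.37 with 19 of 19 members negative (camera adjusted p = 2.93e-09; adjusted p = 0.124 with an estimated correlation), and 10 were lower adjusted over the list alone against 0 over all genes. Among them were Col5a1 (-0.59 ± 0.13), Fn1 (-0.50 ± 0.11), Col1a1 (-0.55 ± 0.16) and Col1a2 (-0.51 ± 0.15), which encode fibrillar collagens and fibronectin. Fibroblast markers had a median of -0.27 with 12 of 13 negative (camera adjusted p = 2.64e-05; adjusted p = 0.0695 with an estimated correlation). Over the list alone 6 were lower, among them Mfap4 (-0.79 ± 0.19), Col13a1 (-0.53 ± 0.14), Npnt (-0.53 ± 0.18) and Gucy1a1 (-0.38 ± 0.14). Smooth muscle markers had a median of -0.44 with 9 of 9 negative (camera adjusted p = 1.78e-07; adjusted p = 0.122 with an estimated correlation). Over the list alone 3 were lower: Hhip, the actin-binding Synpo2 (0.501 of the Flox level) and the smooth muscle myosin Myh11 (-0.66 ± 0.21). The smooth muscle median was -0.79 without EpithelialKO mouse 17. Endothelial markers had a median of -0.37 with 15 of 17 negative (camera adjusted p = 2.93e-09; adjusted p = 0.122 with an estimated correlation). Over the list alone 8 were lower, among them the fenestral diaphragm gene Plvap (-0.50 ± 0.10, 558 to 394 CPM), Ptprb (-0.51 ± 0.12), the VEGF receptor Kdr (-0.45 ± 0.11) and the apelin receptor Aplnr (-0.51 ± 0.13). No member of the fibroblast, smooth muscle or endothelial lists passed over all genes. Mesothelial markers fell (median -0.52, camera adjusted p = 0.00855; adjusted p = 0.493 with an estimated correlation), with 0 members past either threshold, and the call was lost without EpithelialKO mouse 18 and with the adipose score as a covariate (median -0.23). The mesothelial median was -0.28 without Flox mouse 6 and -0.83 without EpithelialKO mouse 21.

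Epithelial lists other than that of AT1 cells rose. Pan-epithelial genes had a median log2 fold change of 0.32 with 13 of 13 positive (camera adjusted p = 1.78e-07; adjusted p = 0.122 with an estimated correlation), and 6 were higher over the list alone against 0 over all genes. Among these were the splicing regulator Esrp2 (0.69 ± 0.14) and the transcription factors Ehf (0.46 ± 0.13), Foxa2 (0.36 ± 0.11) and Nkx2-1 (0.37 ± 0.12). AT2 markers, of the alveolar cells that make surfactant, had a median of 0.25 with 20 of 20 positive (camera adjusted p = 8.57e-08; adjusted p = 0.17 with an estimated correlation). Over the list alone 2 were higher, S100g (0.49 ± 0.11) and the alarmin Il33 (0.43 ± 0.10), while Sftpb (0.31 ± 0.11) and Cebpa (0.26 ± 0.10) did not pass. Il33 is also on the type 2 inflammation list, and Lpcat1 on the lipid synthesis list. Club cell markers had a median of 0.33 with 20 of 21 positive (camera adjusted p = 4.1e-07; adjusted p = 0.301 with an estimated correlation), and Gabrp (0.64 ± 0.13), Aldh1a7 (0.50 ± 0.14) and Cbr2 (0.59 ± 0.18) were higher over the list alone. The club median was 0.11 without Flox mice 4 and 6, 0.21 without Flox mouse 6 alone and 0.51 without Flox mouse 2. Ciliated cell markers had a median of 0.41 with 25 of 25 positive (camera adjusted p = 2.68e-08; adjusted p = 0.303 with an estimated correlation) but 0 members passed either threshold. Fam183b had 0.66 ± 0.19, Tppp3 0.34 ± 0.12 and Deup1 1.04 ± 0.38. The ciliated median was 0.26 without Flox mice 4 and 6 and 0.26 without EpithelialKO mouse 17. AT1 markers, of the flat cells of gas exchange, were not shifted (median -0.03, 6 of 17 positive, camera adjusted p = 0.505). Neuroendocrine markers rose (median 0.64 over 7 members, camera adjusted p = 0.00896; adjusted p = 0.189 with an estimated correlation), at low levels such as 1.14 and 2.92 CPM for Calca, and lost the call under limma-voom and without Flox mouse 5. Of the basal cell list 1 of 7 members was expressed enough to test, so it was not tested as a list.

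**Figure D2:**
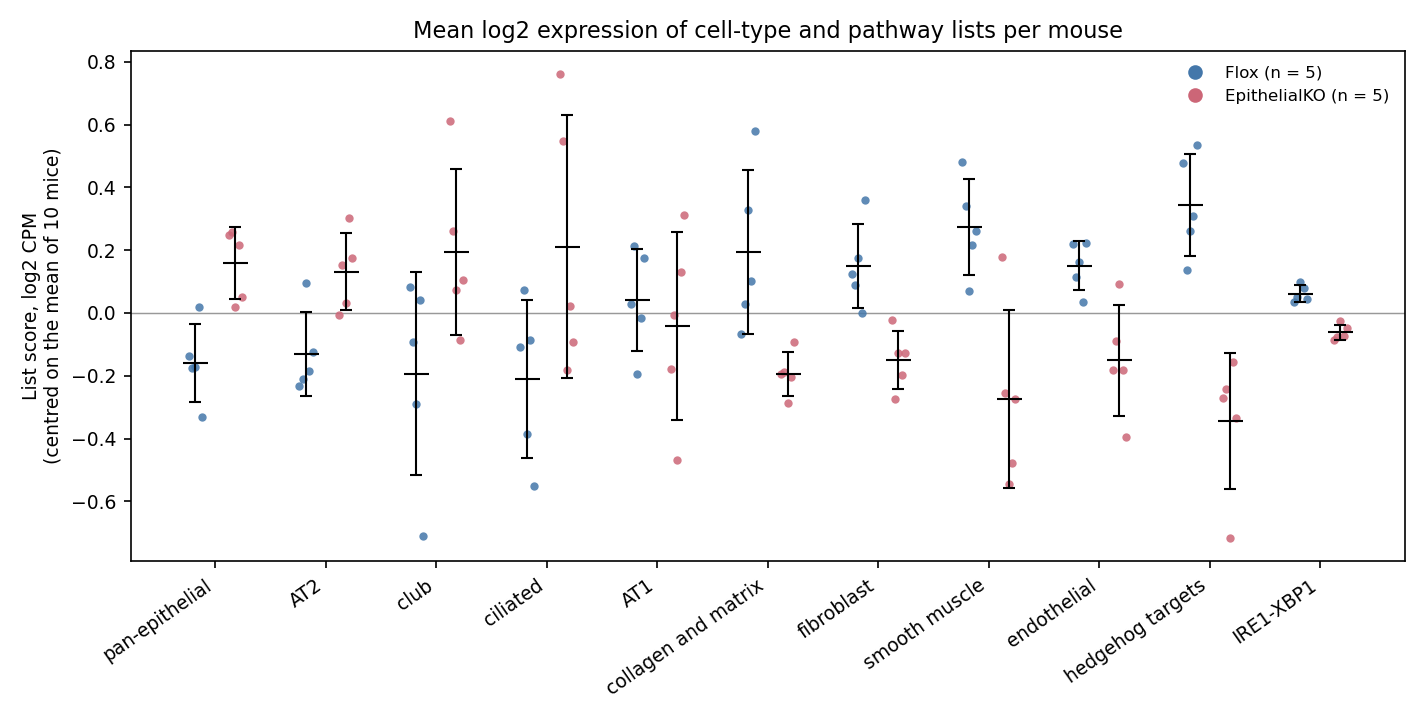
List scores per mouse, the mean log2 CPM of each list's tested members centred on the mean of the 10 mice, for 11 lists, with Flox in blue and EpithelialKO in red, dashes for group means and bars for SD (n = 5). The groups do not overlap for the pan-epithelial, collagen and matrix, fibroblast, hedgehog and IRE1-XBP1 lists, and overlap for the others shown.

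The NRF2 antioxidant and integrated stress response lists rose. The NRF2 list had a median log2 fold change of 0.19 with 12 of 13 positive (camera adjusted p = 8.27e-07; adjusted p = 0.135 with an estimated correlation). Gclc passed over all genes, and 5 members were higher over the list alone, including Hmox1 (0.42 ± 0.11), Gpx2 (0.75 ± 0.20) and Gsta4 (0.50 ± 0.15). The NRF2 median was 0.35 without Flox mouse 2 or 5 and 0.34 under limma-voom. The list of the PERK-ATF4-CHOP integrated stress response had a median of 0.13 with 17 of 27 positive (camera adjusted p = 7.31e-05; adjusted p = 0.124 with an estimated correlation), and 6 members were higher over the list alone against 0 over all genes. Among them were the serine and asparagine synthesis enzymes Psat1 (0.67 ± 0.13, 15.5 to 24.7 CPM) and Asns (0.69 ± 0.15), the transsulfuration enzyme Cth (0.81 ± 0.18) and the cystine transporter Slc7a11 (1.91 to 4.71 CPM). The median of this list was 0.09 without Flox mouse 6 and 0.20 under limma-voom. The heat shock list rose (median 0.25, camera adjusted p = 0.0138; adjusted p = 0.563 with an estimated correlation), with 0 members past either threshold, and lost the call under 7 alternatives. The heat shock median was 0.03 without Flox mice 4 and 6, 0.16 without either of them, 0.15 without EpithelialKO mouse 21 and 0.61 without Flox mouse 5. The Krt8-high transitional list rose (median 0.25, camera adjusted p = 0.0245; adjusted p = 0.501 with an estimated correlation) and lost the call under 9 alternatives, with Krt8 (0.54 ± 0.12) higher over the list alone. Its median was 0.08 without EpithelialKO mouse 22, and 0.13, 0.41 and 0.16 without Flox mice 2, 3 and 5. The hypoxia list was not shifted (median 0.07, camera adjusted p = 0.266), although P4ha2 (0.50 ± 0.14) and Bnip3 (0.42 ± 0.12) were higher over the list alone.

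**Figure D3:**
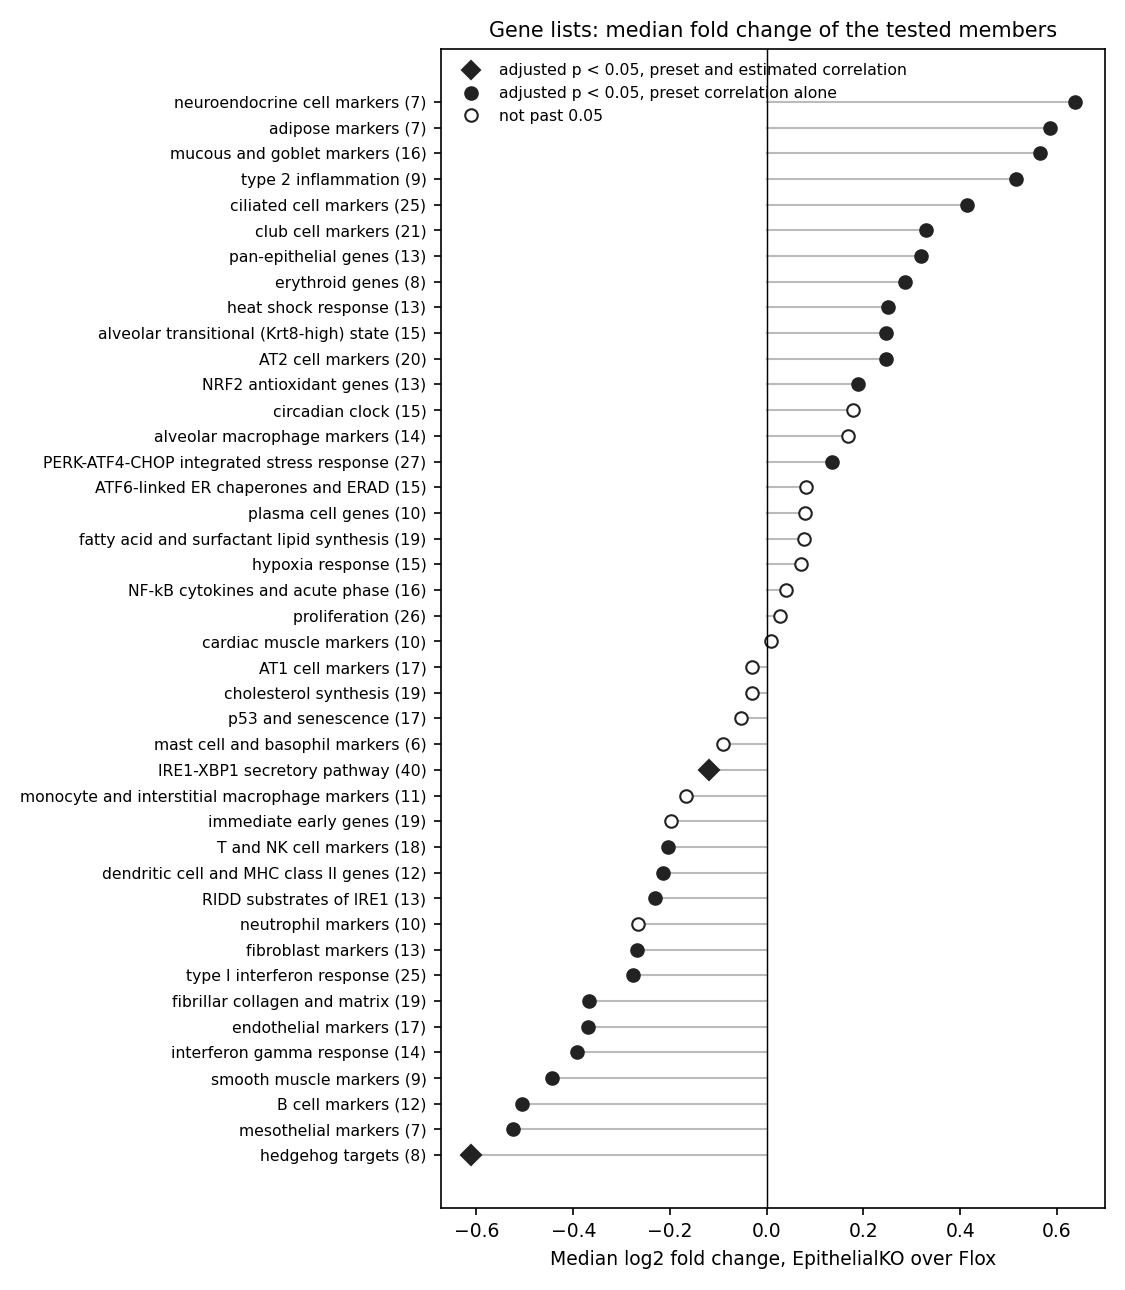
Median log2 fold change of the tested members (their number in brackets) of 42 lists, the sex-linked list left out, with filled symbols for a camera adjusted p under 0.05 with the preset correlation and diamonds where the estimated correlation also passed. The 2 diamonds are the hedgehog targets at -0.61 and the IRE1-XBP1 list at -0.12.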

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

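Set down beforehand were the tests of the number of genes called in edgeR, of the surroundings of Shh, and of the calls kept with sex class or the cardiac score as a covariate. The other tests in this part were chosen after the results were seen. Other tissue and a lower epithelial share had been set down beforehand as explanations of the called genes, but not with the tests used here.

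Of 236 sets of 5 values (total counts, list scores and log2 CPM of the genes the naming rule took, per group), 11 (4.66%) held a mouse that stood apart from the other 4 by more than 0.71 of the group's range, where chance gives about 5%. Flox mouse 5 accounted for 6 of them. Its heat shock list score was 0.953 on the log2 scale against -0.608 to -0.257 in the other Flox mice. Its log2 CPM was 3.03 for Ern1 (others 3.98 to 4.36), 3.21 for Gli1 (others 2.26 to 2.45), 8.07 for Nkx2-1 (others 7.39 to 7.53), 5.35 for Hmox1 (others 5.22 to 5.24) and 9.31 for Hspa5 (others 8.93 to 9.02). Flox mouse 6 had a plasma cell score of -0.873 (others 0.06 to 0.26), Flox mouse 2 an S100g log2 CPM of 6.50 (others 6.93 to 7.03) and Flox mouse 3 a Tppp3 log2 CPM of 9.46 (others up to 9.11). EpithelialKO mouse 17 had a mast cell score of 0.643 (others -0.296 to -0.067), and EpithelialKO mouse 21 an Emilin1 log2 CPM of 4.98 (others 4.59 to 4.68).

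The first pattern weighed was the 6 genes called. Of 100 splits of the 10 mice, the real one included, 3 gave 6 or more genes and the highest other gave 7. This was under the 5% set beforehand by a narrow margin, which argues against chance for that count but does not exclude it. As many as the 1896 genes at an unadjusted p under 0.05 were reached in 5 splits (highest other 2032), so for that count chance was not excluded. The split with 7 exchanged Flox mouse 5 for EpithelialKO mouse 22. The remaining split with 6 set Flox mice 2 and 5 and EpithelialKO mice 17, 18 and 20 against the rest. All 3 splits kept Flox mice 4 and 6, those with high Xist, in the same group, so these counts do not separate genotype from sex. With DESeq2, 1 of 100 splits gave 275 or more genes, and the highest other, which also kept Flox mice 4 and 6 together, gave 264. The mean score of the AT2, AT1, club, ciliated and pan-epithelial lists was 0.26 higher in EpithelialKO (exact permutation p = 0.0317), against a lower epithelial share as the cause. Cardiac muscle is argued against, since 6 of the 6 calls held with the cardiac score as a covariate, but that score does not measure fat or blood, which remain open: 0 calls held with the adipose score (edgeR adjusted p = 0.135 for each), with log2 fold changes of 0.61 for Gclc, -0.87 for Il2rb, -0.85 for Emilin1, -0.65 for Rasgrp3, -0.49 for Specc1l and -0.50 for Sdc3 (SE 0.0881 to 0.156, against 0.0776 to 0.142 without it), and 3 held with the erythroid score, the others being at -0.65 ± 0.13 (SE) for Rasgrp3, -0.51 ± 0.09 for Sdc3 and -0.87 ± 0.16 for Emilin1, against -0.69 ± 0.11, -0.51 ± 0.08 and -0.86 ± 0.14 without it. Sex remains open: 0 of the 6 calls held with sex class as a covariate, the outcome set beforehand as pointing to sex, but leaving out 9 of the 10 single mice also ended every call, and among the 8 mice with Y-linked counts the log2 fold changes were 0.60 for Gclc, -0.83 for Il2rb, -0.67 for Emilin1, -0.65 for Rasgrp3, -0.53 for Specc1l and -0.49 for Sdc3 (SE 0.0993 to 0.169, against 0.0776 to 0.142 in all 10; edgeR adjusted p = 0.214 for each). Variation carried along with the Shh-Cre allele remains open for Emilin1, 2.45 Mb from Shh and the only call among 176 tested genes within 10 Mb (Fisher's exact p = 0.0671).

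The second pattern was the rise of epithelial lists with the fall of stromal and endothelial lists. Of the 100 splits 3 called 26 or more lists, the highest other called 27 and the median other 13, so the preset correlation calls many lists in arbitrary splits. Fold changes fell with transcript length (Spearman's rho across genes -0.27, genes not being independent; medians 0.12 in the shortest 10% and -0.12 in the longest 10%), but over the 8 epithelial and 5 stromal lists classed as such beforehand, AT1 included, the epithelial minus stromal score was 0.74 higher in EpithelialKO with length and GC smoothed out and 0.79 higher without (exact permutation p = 0.00794, the smallest possible, in both), and in the 8 mice with Y-linked counts it was 0.71 higher (exact permutation p = 0.0179, the smallest possible). This argues against length and sex as the whole cause of that contrast. Sex stays open for the club list, whose median was 0.33 in all mice and 0.11 without Flox mice 4 and 6. A larger share of epithelium in the tissue taken would raise AT1 markers with the other epithelial lists. The AT1 score minus the other epithelial scores was 0.43 lower in EpithelialKO, against that direction. Its exact permutation p of 0.0635 did not pass, so this explanation stays open. An effect of the genotype on cell composition or on expression within cells is a biological explanation that stays open.

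The third pattern was the fall of the hedgehog and IRE1-XBP1 lists, the 2 called with an estimated correlation. Of the 100 splits 1, the real one, called as many lists in that way, and the highest other called 1. That test was chosen after the result and covers the number of lists called, not these 2 lists. Each of the 2 had an exact permutation p of 0.00794, the smallest possible, and 0.0683 after adjustment, so chance was not excluded for them. With the length and GC offset and an estimated correlation the adjusted p was 0.0312 for the hedgehog and 0.0193 for the IRE1-XBP1 list. Their medians with the offset were -0.49 and -0.16, against -0.61 and -0.12 without it. This argues against length bias as the whole cause, although a Spearman's rho of -0.07 between fold change and length remained with the offset. Sex stays open, since without Flox mice 4 and 6 the adjusted p with an estimated correlation was 0.0871 for both, with medians of -0.45 and -0.13. Fewer mesenchymal cells would lower the hedgehog list as much as the fibroblast and smooth muscle markers. The hedgehog score without Hhip, less that of those markers, differed by -0.25, a further fall. It did not pass (exact permutation p = 0.111), so this explanation stays open. Fibroblast markers were also called with the offset and an estimated correlation (median -0.29, camera adjusted p = 0.0441). Hypotheses that the design names are that replacing 1 Shh copy with Cre lowers hedgehog signalling, for which Shh itself had a log2 fold change of -0.0268 in counts that cannot tell the alleles apart, and that loss of epithelial IRE1α lowers XBP1 targets, for which the IRE1-XBP1 score minus the ATF6-linked score was 0.13 lower in EpithelialKO (exact permutation p = 0.206). None of these tests separates the Cre allele from the loss of Ern1, because the labels give both to all EpithelialKO mice, and the counts do not check either.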

How the results depend on the processing

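The fit without Flox mice 4 and 6 and the alternatives on the adipose and erythroid scores and on transcript length and GC were chosen after seeing the data. Fits with sex class and with the cardiac score had been set down beforehand as tests of the called genes, and were added as alternatives after seeing the data. The planned sex covariate required both sexes in both groups and was not run as planned, because high Xist without Y-linked counts occurred in Flox alone. It was run as an added alternative. Sex class sets apart only Flox mice 4 and 6, so that fit nearly repeats the fit without them. The Il2rb log2 fold change, for example, was -0.833 and -0.832, so the fits are not separate evidence. No replicate number is shared between the groups. No paired analysis was possible because the groups compared share fewer than 2 numbers. The 6 genes called (1 higher, 5 lower) became 275 with DESeq2 (106 higher, 169 lower), 32 with limma-voom (12 and 20), 34 with no low-count filter (12 and 22), 83 with 1 surrogate variable (30 and 53) and 38 at a threshold of 0.1 (13 and 25), and each of these sets held all 6. Higher calls were 2 with upper-quartile scaling (8 in all) and 2 with the cardiac score (8 in all). Leaving out 1 mouse gave 0 to 48 genes (0 to 17 higher, 0 to 31 lower): 0 in 9 of 10 fits and 48 without Flox mouse 5. There were 0 calls without Flox mice 4 and 6 (1207 genes at an unadjusted p under 0.05) and 0 with the adipose score (1589 genes). With the erythroid score 4 were called (1 higher, 3 lower), 3 of them among the 6. With sex class as a covariate 1 gene was called, 1 higher and 0 lower, and none of the 6; it was Nrn1 (0.94), chosen after its value was seen. With the length and GC offset there were 3 (2 higher, 1 lower): Gclc, Il2rb and Epn3 (0.59), the last chosen after its value was seen. Rasgrp3 (-0.68, edgeR adjusted p = 0.0513), Emilin1 (-0.74, 0.0734), Specc1l (-0.41, 0.0734) and Sdc3 (-0.37, 0.116) did not pass with that offset. Why the calls were lost was not tested. All 6 genes kept their direction in 24 alternatives, which was likely from the start because they were called in the same mice. Their adjusted p ranged from 2.15e-06 in DESeq2 to 0.214 in edgeR without Flox mice 4 and 6.

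The 26 lists became 2 with an estimated correlation, 3 with it and the length and GC offset, and 0 with it without Flox mice 4 and 6. The third list with the offset was that of fibroblast markers (camera adjusted p = 0.0441). They became 0 in the exact permutation test, with z scores and with a prior count of 0.5. With the preset correlation, 24 alternatives gave 21 to 29 lists; 15 of the 26 were called in all of them, and 11 lost the call in at least 1. The median turned sign for T and NK cells without Flox mice 4 and 6 (0.0174) and with sex class (0.0163), for the mucous list with the adipose score (-0.0706) and for the erythroid list with its own score (-0.0824). A list's own score as a covariate takes up its shift by construction, so the erythroid turn says nothing about stability. The mast cell list, not shifted otherwise, was higher with sex class (0.59, camera adjusted p = 0.0443 with the preset correlation). Without Flox mice 4 and 6 its median was also 0.59, but the camera adjusted p was 0.053 with the preset and 0.284 with an estimated correlation.

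The Ern1 log2 fold change, not past the threshold, was -0.11 with limma-voom and -0.0404 with the adipose score, and ranged from -0.16 to 0.17 over the fits without 1 mouse: -0.13 without Flox mouse 5, -0.06 without EpithelialKO mouse 21 and -0.16 without EpithelialKO mouse 22. Xbp1 ranged from -0.0339 to 0.12 over those fits and turned to -0.02 without Flox mouse 6, -0.0339 without EpithelialKO mouse 21, -0.0270 without Flox mice 4 and 6 and -0.0284 with sex class as a covariate. Shh ranged from -0.23 to 0.16 over the same fits and turned to 0.0908 with limma-voom, 0.14 with the adipose score, 0.16 without Flox mouse 5, and 0.00755, 0.00457 and 0.0948 without EpithelialKO mice 17, 18 and 22. The list members that the rule for named genes took besides the called genes, 65 in number, kept their direction in all 1560 fits. They had been taken for the lowest p in the main fit and the alternatives reuse the same mice, so a kept direction was likely from the start.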

Other observations

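Among immune and inflammatory genes, the list of the type I interferon response had a median log2 fold change of -0.28 with 24 of 25 members negative (camera adjusted p = 1.26e-05; adjusted p = 0.189 with an estimated correlation). Over the list alone 3 were lower, Ddx60 (-0.90 ± 0.27, SE), Ifi44 (-0.62 ± 0.19) and Bst2 (-0.31 ± 0.10), against 0 over all genes. The interferon gamma list fell (median -0.39, camera adjusted p = 0.00123; adjusted p = 0.475 with an estimated correlation), with the peptide transporter Tap1 (-0.45 ± 0.12) and the guanylate-binding Gbp3 (-0.54 ± 0.17) lower over the list alone, and lost the call without Flox mouse 3 (median -0.13). Its median was -0.25 without Flox mice 4 and 6. T and NK cell markers fell (median -0.20, camera adjusted p = 0.00318; adjusted p = 0.503 with an estimated correlation). Their 1 member lower over the list alone was the perforin gene Prf1 (-0.89 ± 0.20), and the call was lost without Flox mouse 4 (median -0.11), and both the call and the sign of the median were lost without Flox mice 4 and 6 (0.0174) and with sex class as a covariate (0.0163). Without EpithelialKO mouse 20 it was -0.32. B cell markers fell (median -0.51, 12 of 12 negative, camera adjusted p = 5.24e-05; adjusted p = 0.362 with an estimated correlation) with 0 members past either threshold and Fcrla at -0.55 ± 0.19. Their median was -0.29 without Flox mouse 4 and -0.30 without Flox mice 4 and 6. Dendritic cell and MHC class II genes fell (median -0.21, camera adjusted p = 0.0158; adjusted p = 0.454 with an estimated correlation) and lost the call under 6 alternatives, with a median of -0.13 without Flox mouse 4, without Flox mice 4 and 6 or without EpithelialKO mouse 22. The type 2 inflammation list rose (median 0.51 over 9 members, camera adjusted p = 0.00123; adjusted p = 0.17 with an estimated correlation), with Retnla (0.92 ± 0.19, 54.9 to 103 CPM) and Il33, also on the AT2 list, higher over the list alone; its cytokines Il4, Il5 and Il13 were too low to test. Clca1 is on both this list and the mucous list.

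The alveolar macrophage list was not shifted (median 0.17, camera adjusted p = 0.199), yet over the list alone the scavenger receptor Marco was lower (-0.74 ± 0.14, SE, 25.4 to 15.2 CPM) and Pparg higher (0.60 ± 0.15). This list was called in 4 of 24 alternatives with the preset correlation. Its median was 0.39 without Flox mice 4 and 6 (camera adjusted p = 0.0104; adjusted p = 0.595 with an estimated correlation). Mucous and goblet markers rose (median 0.57, camera adjusted p = 0.0385; adjusted p = 0.563 with an estimated correlation) and lost the call under 11 alternatives (median 0.18 without EpithelialKO mouse 17, 0.86 without Flox mouse 4); Bpifa1 stood at 104 ± 135 CPM in Flox and 485 ± 547 CPM in EpithelialKO (SD, n = 5 each). Adipose markers (median 0.59, camera adjusted p = 0.0367; adjusted p = 0.493 with an estimated correlation) and erythroid genes (median 0.29, camera adjusted p = 0.0351; adjusted p = 0.53 with an estimated correlation) rose with 0 members past either threshold, and lost the call under 9 and 12 alternatives. Each of these counts includes the fit with the list's own score, where the loss was fixed in advance. The adipose median was 1.15 without Flox mouse 4, 1.01 without Flox mice 4 and 6 and 0.32 without EpithelialKO mouse 18. The erythroid median was 0.57 without Flox mouse 2, 0.18 without Flox mouse 4, 0.17 without Flox mice 4 and 6 and 0.09 without EpithelialKO mouse 20. The lists not shifted, with their median log2 fold change, were cardiac muscle (0.01), neutrophils (-0.27), monocytes and interstitial macrophages (-0.17), plasma cells (0.08), mast cells and basophils (-0.09), NF-kB cytokines (0.04), p53 and senescence (-0.05), cholesterol synthesis (-0.03), fatty acid and surfactant lipid synthesis (0.08), proliferation (0.03), circadian clock (0.18), immediate early genes (-0.20) and sex-linked genes (0.79). Some of these lists were called under alternatives with the preset correlation. Immediate early genes were called in 6 of 24 (median -0.40 without Flox mice 4 and 6) and neutrophils in 5. Monocytes and interstitial macrophages, proliferation and the circadian clock were called in 3 each, and the others in 2 at most. The median, mean and test differed in sign for the hypoxia, mast cell, NF-kB and sex-linked lists.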
